A study of Mus musculus with 2 samples.

How the data were processed

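Single CD4 T cells from mouse spleen were measured by SmartSeq2, a full-length RNA-seq method for cells sorted into the wells of a plate. The cells carried the OTII T cell receptor, a transgenic receptor specific for ovalbumin, and had been transferred into host mice. Each of the 2 samples was a pool of mice, with 2 control hosts (C57BL/6) in one and 3 hosts with a floxed Il13ra1 gene and CD11c-Cre in the other. CD11c-Cre acts mainly in dendritic cells of the host, so the receptor gene was deleted there and not in the transferred cells. Cells were collected on day 7 after CAS and the second priming, an abbreviation that the labels do not explain. The sort gate took viable (propidium iodide negative), V beta 5.1/5.2 positive, CD4 positive cells, and no congenic marker was named, so host CD4 cells with V beta 5 could also pass it.

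The authors deposited whole-number read counts per gene and well, without normalization. Per the labels' protocols, cDNA was primed with oligo(dT), amplified with 25 PCR cycles and tagmented with Tn5 before paired-end sequencing. The submitters' processing notes name featureCounts 2.0.1 and the genome build mm10. The aligner, annotation, strand setting and treatment of reads that map to several places are not given in the sources used here. Reads of a gene and its antisense partner therefore cannot be told apart, and genes with near-identical copies may have lost or shared reads. The protocol names no molecular identifiers, and PCR copies of a molecule count as separate reads, so intervals cover the counting error of reads or cells only.

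The 35976 gene rows were the same in all 8 plates. Each plate had 96 wells, of which 92 were cell wells and 4 were control wells with names ending in mBM10, mBM100, noinput or dw. The 32 control wells entered no comparison. Plates are called control plate 1 to 4 and deleted plate 1 to 4, in the order of the plate labels. Reads in genes were summed over the cells of each plate and pool. No cell well was removed from the main values, including 1 with under 10000 reads. That well, A12 of deleted plate 4, held 9905 reads and 331 genes with at least 5 reads. Both values lie inside the range of the noinput and dw wells, so it may have held no cell. No doublet caller was run, since cells were sorted into separate wells.

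With 1 pooled sample per group there was no test between groups, and no p-value or standard error is given. Plates of a pool are technical splits of the same animals. Plate and pool cannot be told apart, since no plate held cells of both. For each gene, counts scaled to a total of 1000000 reads in genes (CPM) were computed per pool, with an exact Poisson 95% interval, and per plate. The log2 ratio is log2 of (CPM in deleted hosts + 1) over (CPM in control hosts + 1), so folds of low genes are understated. A gene was called separated when every plate of one pool lay above every plate of the other, which has a 2.86% chance for exchangeable plates. A cell was called positive for a gene at 10 CPM or more and at least 5% of the gene's mean CPM on its plate. Shares of cells have exact (Clopper-Pearson) 95% intervals. A share of 0 was given an upper limit of 3 counts.

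Fixed before the data were examined were 24 gene lists, 11 lists of cell type markers, the comparisons, the alternative settings and the rule for naming genes. List members with 5 CPM or more in either pool were measured. A list's median log2 ratio has an exact binomial order-statistic interval over its members and a percentile among 10000 random lists of the same size, drawn from 20 expression bins. Random lists hold independently drawn genes, and medians of co-regulated genes spread more than theirs, so a percentile near 0 or 100 describes these libraries and is not a test. List symbols without a row in the tables, 13 in all, were not analysed here. A member counted as higher or lower at a log2 ratio of at least 1 in size, a rule of size and not a test.

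Named genes were, first, the 12 largest ratios in each direction among separated genes with 20 CPM or more in the higher pool, leaving out predicted genes. Next came up to 4 members per list with the largest ratios at 20 CPM or more, while all measured members of the 6 helper cell lists could be named. The last part was a fixed set that included Il13ra1, Il4ra, Bcl6, Cxcr5, Pdcd1, Icos, Il21, Foxp3 and Ifng, and some genes that the rule names are not reported here. Genes singled out at 100 CPM or more were chosen after their values were seen, as stated where they appear, and so were the members behind a count of 5 or fewer in a list. Coordinates are from the NCBI RefSeq annotation of GRCm38.p6, the assembly also called mm10.

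Cells with 10000 reads or more were clustered on 1500 variable genes, after leaving out separated genes, the activation list and the immediate early list. Log-scaled values were standardised, reduced to 10 principal components and split by k-means into 3 clusters, which are called by number only. Alternatives covered the scaling of pools (edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors), plate weights, thinning, pseudocounts of 0.1 and 10 CPM, filters, cell quality and each plate left out in turn. Another 3 alternatives were added after seeing the data. The work used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.

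The scripts were tested on simulated plates of the comparison between the pools, with 9241 genes of which 200 were changed. Genes changed by a log2 ratio of 1 or -1 were estimated at medians of 0.95 and -1.06, and those changed by 2 or -2 at 1.89 and -1.92. Of the genes left unchanged, 2.95% were separated. Of 40 unchanged lists of independently simulated genes, 1 lay outside the middle 95% of random lists. With 1 added to the estimated log2 ratio of each member, 40 of 40 lay above it. Lists of co-regulated genes were not simulated. The pools held 573105030 and 542650671 reads, and the limits set by depth, cells and animals were not compared.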

Results

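The study asked how IL-13 receptor signalling in dendritic cells bears on the development of T follicular helper (TFH) cells, the CD4 T cells that help B cells make antibody. OTII CD4 T cells were recovered from the spleens of control hosts or of hosts with Il13ra1 deleted in CD11c-expressing cells, on day 7. Each group was 1 pooled sample of 368 cell wells on 4 plates, from 2 control and 3 deleted hosts. The control pool held 573105030 reads, with 137968663 to 148025125 per plate and a median of 1592794 per cell. The deleted pool held 542650671 reads, with 125197307 to 143937319 per plate and a median of 1499762 per cell. A median of 4287 genes per control cell and 4486 per deleted-host cell had at least 1 read. Wells without a cell also had 3112 to 4472 genes with at least 1 read, so this count may hold background. With at least 5 reads, plate medians were 1510.5 to 1626 genes per control cell and 1520.5 to 1560 per deleted-host cell. Wells without a cell had 181 to 439 genes at that level. There were no biological replicates, so all differences below are without a replicate check, and intervals cover counting error only.

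The sorted cells were CD4 T cells in both pools. Cd4 was at 915 CPM in control hosts and 783 CPM in deleted hosts, and Cd3e, a chain of the T cell receptor complex, at 221 and 212 CPM. The 9 CD4 T cell markers had a median log2 ratio of -0.06 and summed to 7910.4 CPM in control and 8005 CPM in deleted hosts. Il13ra1 itself (chromosome X, 36112108 to 36171262, GRCm38) was at 2.35 CPM in control and 0.197 CPM in deleted hosts, with 1 positive cell in each pool. The deletion was in host cells, so this level checks nothing about the labels. Without the highest cell of each pool its log2 ratio was 0.06. Il4ra, which encodes the receptor chain shared by IL-4 and IL-13, was at 262 and 243 CPM. Il13 had almost no reads (0.014 CPM in control and 0 CPM in deleted hosts).

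The genes that define TFH cells were at similar levels in the pools. Bcl6, the transcription factor that directs TFH development (chromosome 16, 23965050 to 23988866), was at 31.0 CPM in control hosts, with plates from 15.3 to 56.2, and at 23.8 CPM in deleted hosts, with plates from 14.2 to 29.4. Cxcr5, the receptor that leads T cells to B cell follicles, was at 139 and 167 CPM. Pdcd1, an inhibitory receptor abundant on TFH cells, was at 111 and 145 CPM, and the costimulatory receptor gene Icos at 225 and 277 CPM. For each of these 4 genes the plates of the pools overlapped. Cells positive for both Cxcr5 and Pdcd1 made up 2.72% of each pool (10 cells, interval 1.31 to 4.94%). Il21, the TFH cytokine, was positive in 4 control and 5 deleted-host cells (3.75 and 6.10 CPM). Il4 was positive in 4 cells of each pool (1.94 and 4.46 CPM). With 1 plate left out, their log2 ratios ranged from 0.21 to 1.34 for Il21 and from -0.12 to 1.24 for Il4.

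**Figure D1:**
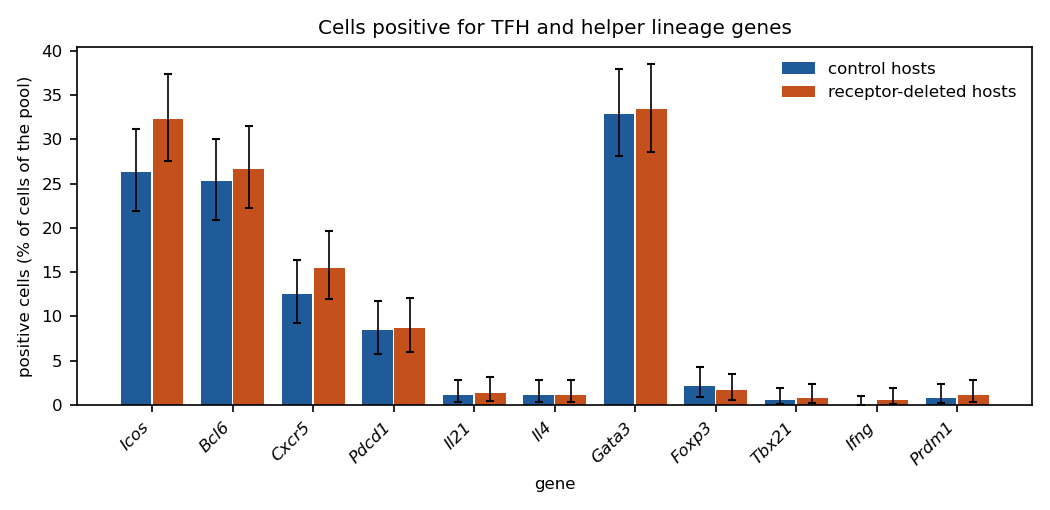
Percentage of the cells of each pool that were positive for TFH and helper lineage genes (bars, y axis; genes on the x axis), with exact 95% binomial intervals that cover counting error only. Icos was positive in 26.4% of control and 32.3% of deleted-host cells, Bcl6 in 25.3% and 26.6%, and the intervals of the pools overlap for every gene shown.

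Of the 27 measured members of the TFH list, 6 were higher in deleted hosts, 1 was lower and 20 lay within 2-fold. Id3, an inhibitor of E proteins, was the lower one and the only member at 100 CPM or more to differ by 2-fold, at 522 CPM in control and 203 CPM in deleted hosts. The 6 higher members were Angptl2, Sostdc1, Pou2af1, Ascl2, Tox2 and Rgs16, each at 54.5 CPM or less. With 1 plate left out, each of these but Angptl2 fell under 2-fold, with log2 ratios of 0.59 for Ascl2 (without deleted plate 3), 0.62 for Rgs16 (without control plate 4), 0.78 for Pou2af1 (without control plate 3) and 0.87 for Tox2 (without deleted plate 1) at the lowest. Ascl2, a transcription factor of early TFH cells, was at 5.36 and 12.4 CPM in 11 and 12 positive cells. Tox2 was the separated one, at 18.5 and 39.998 CPM. Sostdc1 (24.2 and 54.5 CPM) rested on 3 and 4 positive cells, and its log2 ratio was -0.30 without deleted plate 1. Tcf7 and Lef1, transcription factors of resting and TFH cells, had log2 ratios of 0.16 and -0.04. The list's median log2 ratio was 0.14 (interval -0.10 to 0.38), at the 98.9th percentile of random lists. It was 0.01 with a minimum of 20 CPM, 0.04 without control plate 2 and 0.05 without deleted plate 4.

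Of the 13 measured genes that oppose the TFH programme, each lay within 2-fold. Their median log2 ratio was 0.24 (interval -0.13 to 0.61, 99.8th percentile), with 9 members above 0 and 4 below, and it was 0.37 without control plate 3. Gpr183, a receptor for oxysterols that keeps cells at the follicle edge, was at 256 CPM in control and 391 CPM in deleted hosts and was separated. S1pr1, which lets T cells leave lymphoid tissue, was at 400.4 and 529.6 CPM, and Klf2, its transcriptional activator, at 203 and 248 CPM. Id2 went the other way, at 254 and 200.2 CPM. Prdm1, which represses Bcl6, was under the minimum of 5 CPM and so not among the 13. It was at 1.33 and 4.07 CPM, in 3 and 4 positive cells. Its log2 ratio of 1.12 was -0.46 without deleted plate 3.

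The Treg, TH1 and TH17 medians also lay above the middle 95% of random lists, and the higher members of TH1 and TH17 were positive in at most 22 cells of a pool. The 15 measured Treg genes had a median log2 ratio of 0.65 (interval 0.16 to 0.90, above all 10000 random lists), with Klrg1, Gpr83 and Nrp1 higher (Gpr83 at 0.97 without control plate 3 and Nrp1 at 0.88 without control plate 4). Of the 15 members, 12 had a log2 ratio above 0 and 3 below, the lowest at -0.59. Ctla4, an inhibitory receptor, was positive in 19.0% of control and 33.2% of deleted-host cells (98.6 and 168 CPM). Tnfrsf9 was at 128 and 223 CPM. Foxp3, the Treg transcription factor, was positive in 8 control and 6 deleted-host cells, and its log2 ratio of 0.90 was -0.44 at the lowest when 1 plate was left out. Klrg1 was positive in 0 control cells, which allows a share of up to 0.815%, and in 3 deleted-host cells. The Treg median was 0.21 without deleted plate 3, 0.999 without control plate 1, 0.73 with a minimum of 20 CPM and 0.74 without the highest cell of each pool.

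Among 14 measured TH1 genes, Ly6c2, Il18r1 and Eomes were higher and Tnf was lower. Eomes, a T-box transcription factor, was separated at 19.7 CPM in control and 67.0 CPM in deleted hosts. Its log2 ratio of 1.72 was 1.10 without deleted plate 3, and that of Il18r1 (1.84) was 1.18 without deleted plate 3 and 3.18 without control plate 2. Markers of natural killer and other innate lymphoid cells, some of which also express Eomes, summed to 33.8 and 54.9 CPM with no overlap between plates. Of these 11 markers only 2 reached 5 CPM in either pool, so the sum does not give an amount of such cells. Tnf was at 23.6 and 3.75 CPM, with 13 and 5 positive cells. Ly6c2 had 1 and 3 positive cells, and its log2 ratio was -0.10 without deleted plate 3. Tbx21, the main TH1 transcription factor, was at 2.46 and 5.32 CPM, and Ifng had 0 positive control cells and 2 positive deleted-host cells. The TH1 median of 0.53 (interval -0.46 to 1.72, 99.4th percentile) was 0.01 without deleted plate 3, 0.18 without control plate 3, 0.34 without deleted plate 2, 0.83 without deleted plate 4 and -0.14 with a minimum of 20 CPM.

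The TH2 list had 5 measured genes and a median log2 ratio of 0.20 (81.5th percentile), and Nfil3 alone was higher, with 1 and 7 positive cells and a log2 ratio of 0.69 without deleted plate 3. Gata3, the TH2 transcription factor, was at 271 CPM in control and 311 CPM in deleted hosts. Leaving out 1 plate gave TH2 medians from 0.02 to 0.44. Of 5 measured TH17 genes, Il22, Ccr6 and Il1r1 were higher and Tmem176b was lower. Il22 came from 1 deleted-host cell, Il1r1 had a log2 ratio of 0.54 without deleted plate 3, Ccr6 was positive in 3 deleted-host cells, and Tmem176b had a log2 ratio of 0.90 without control plate 2. The TH17 median was 1.51 (99.2nd percentile). It was 0.37 without deleted plate 3, 0.76 without the highest cell of each pool and 0.27 with no filter on low counts.

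At 100 CPM or more, 150 of 2388 genes were separated (6.28%, against 2.86% by chance), 58 higher and 92 lower in deleted hosts, and 9 were at least 2-fold higher and 6 at least 2-fold lower. Dusp5, a phosphatase that inactivates ERK (chromosome 19, 53529145 to 53541809), was at 36.5 CPM in control hosts (plates 25.7 to 48.4) and 218 CPM in deleted hosts (plates 153 to 278), a 5.83-fold difference. Its share of positive cells was 11.96% (interval 8.82 to 15.7%) in control and 38.3% (33.3 to 43.5%) in deleted hosts. Tnfaip3, which encodes the NF-kappaB inhibitor A20 (chromosome 10, 19000910 to 19015410), was at 137 and 512 CPM, 3.72-fold higher, in 17.7% (13.9 to 22.0%) and 49.5% (44.2 to 54.7%) of cells. Both belong to the 12 largest separated genes. The following genes, at 100 CPM or more, were singled out after their values were seen. Rgs2, a regulator of G protein signalling, was at 71.8 and 238 CPM, Rgs1 at 102 and 214 CPM, and the ubiquitin ligase gene Cblb, a brake on T cell activation, at 116 and 249.9 CPM. Junb, a subunit of the AP-1 transcription factor, was at 1285 and 2889.9 CPM, Klf6 at 266 and 551 CPM, Vgll4 at 43.3 and 121 CPM, and Runx1 at 55.1 and 115 CPM. Together with Dusp5 and Tnfaip3 these were the 9 separated genes that were at least 2-fold higher at this level.

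At least 2-fold lower in deleted hosts at this level were 6 separated genes, likewise singled out after their values were seen. Id3 (chromosome 4, 136143822 to 136145392) was positive in 47.3% (42.1 to 52.5%) of control and 29.3% (24.7 to 34.3%) of deleted-host cells, a 2.56-fold lower level. Egr1, an immediate early transcription factor (chromosome 18, 34861207 to 34864956), was at 296 CPM in control hosts (plates 173 to 482) and 116 CPM in deleted hosts (plates 94.0 to 136). Ripk3, a kinase of necroptosis, was at 123 and 49.6 CPM, Ap3m1 at 108 and 48.8 CPM, Anapc4 at 119 and 55.2 CPM, and H2-K2 at 118 and 54.0 CPM. H2-K2 has close relatives among the class I genes, so its reads may be shared. With the plate that carried most of the difference left out, Cblb, Klf6, Rgs1, Runx1, Ripk3, Ap3m1, Anapc4 and H2-K2 were less than 2-fold apart (log2 ratios of 0.92, 0.93, 0.85, 0.77, -0.99, -0.88, -0.85 and -0.97).

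**Figure D2:**
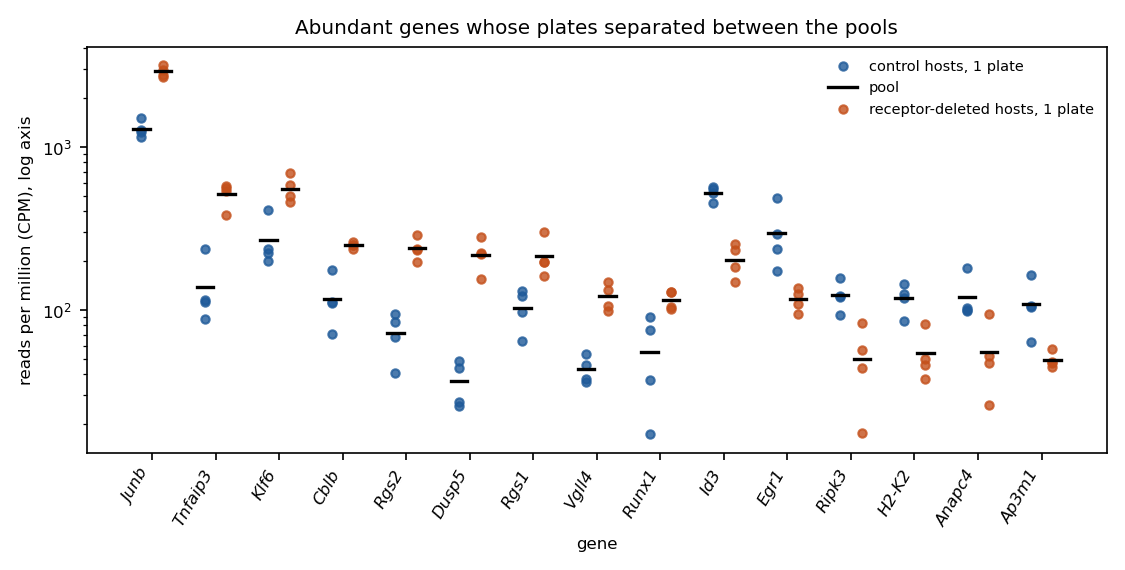
CPM (y axis, log scale) of the 15 genes (x axis) that had at least 100 CPM in the higher pool, were at least 2-fold apart and had no overlap between plates. Points are plates (4 per pool, blue for control and orange for deleted hosts) and black lines the pools; Dusp5 plates span 25.7 to 48.4 CPM in control and 153 to 278 CPM in deleted hosts.

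Across genes with 20 CPM or more in the higher pool, 337 of 7207 were separated (4.68%, against 2.86% by chance), 131 higher and 206 lower in deleted hosts. The 12 largest higher genes included Lrp12 (0.869 and 20.1 CPM), the transcription factor gene Creb3l2 (3.07 and 20.2 CPM), the choline kinase gene Chka (4.93 and 25.5 CPM), Odc1, which starts polyamine synthesis (16.4 and 68.6 CPM), Mgat4a (15.5 and 64.3 CPM) and Gadd45g (5.95 and 23.6 CPM). Siae, Hhat, Dennd4c and Cdc20 completed them with Dusp5 and Tnfaip3. Apart from these last 2 genes, the higher genes too were read in few cells, from 1 to 16 positive control cells and from 8 to 29 in deleted hosts, and Siae (8.58 and 37.6 CPM) had 10 and 8. The 12 largest lower genes were Nek1, Gtf3c4, Gmppb, Zfp874a, Cluh, Mettl4, Abhd2, Wdr73, Ifit3, Mmab, Evi5l and Mrps2. Nek1, a kinase gene, was at 27.4 CPM in control and 2.25 CPM in deleted hosts, and Wdr73 at 36.5 and 6.80 CPM. Each of these 12 lower genes was read in few cells, from 5 to 22 positive control cells and from 2 to 8 in deleted hosts.

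The list of immediate early and heat shock genes had a median log2 ratio of 0.47 (17 measured, interval 0.22 to 0.73), above all 10000 random lists. Klf4, Junb and Klf6 were higher, and none was lower (0.89 for Klf4 without deleted plate 4). Dusp1, a phosphatase of stress kinases, was at 656 and 1228 CPM and Jun at 284 and 471 CPM, both separated. The 22 activation genes had a median of 0.16 (interval -0.05 to 0.53, 99.3rd percentile) and went both ways. With 1 plate left out this median ranged from 0.04 (without deleted plate 2) to 0.30 (without deleted plate 4), and it moved by over 1.5 times without any 1 of the plates other than deleted plate 1. Cd69, an early activation marker, was separated at 303 and 588 CPM, while Egr1 and Egr3 (30.7 and 12.8 CPM) were lower and Dusp4 and Irf8 higher (without deleted plate 3, Egr3 had a log2 ratio of -0.86 and Irf8 of 0.92). Nr4a1, a reporter of receptor signalling, was at 929 and 1344 CPM with overlapping plates, as was Egr2 at 133 and 69.6 CPM, both singled out after their values were seen. The 16 coinhibitory and anergy genes had a median of 0.27 (interval -0.16 to 0.62, 99.2nd percentile), with Rnf128 and Cblb higher and Ndrg1 lower (0.09 for Rnf128 without deleted plate 3 and -0.48 for Ndrg1 without control plate 3). The median was 0.13 without control plate 3 and 0.16 without deleted plate 4.

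Of 32 measured proliferation genes, 10 were higher (each positive in at most 11 cells of a pool) and none was lower, and the median log2 ratio was 0.39 (interval 0.00 to 1.10, above all 10000 random lists). Cdc20, an activator of the anaphase-promoting complex, was separated at 7.72 and 41.2 CPM, in 4 and 11 positive cells. Mcm7, a subunit of the replicative helicase, was separated at 82.3 and 145 CPM, while Mcm5 was at 87.2 and 45.3 CPM. The median was 0.20 without control plate 2, 0.24 without deleted plate 2 and 0.07 with a minimum of 20 CPM.

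Genes of cytokine signalling and of trafficking stayed within 2-fold with few exceptions. The 9 measured IL-4 and IL-13 signalling genes had a median of 0.26 (interval -0.07 to 0.87, 99.4th percentile), which was 0.14 without control plate 3 and 0.11 without deleted plate 4, and the suppressor of cytokine signalling Cish alone was higher, at 8.27 and 29.7 CPM, with a log2 ratio of 0.96 without deleted plate 3. Socs3 was at 56.8 and 104 CPM. The 13 IL-2 and STAT5 genes had a median of 0.17 (97.1st percentile, up to 0.36 without deleted plate 3) and the 14 IL-6, IL-21 and STAT3 genes 0.02 (74.7th percentile, from -0.08 without control plate 1 to 0.16 without control plate 3). The 19 chemokine receptor and trafficking genes had a median of 0.26 (99.9th percentile) that was 0.11 without control plate 3 and 0.16 without deleted plate 2. The 16 genes of costimulation and B cell help had a median of 0.16 (98.4th percentile), 0.09 without control plate 2 and 0.08 without deleted plate 4, among them Ly9 at 82.7 and 137 CPM and Cd84 at 157 and 248 CPM. The 18 naive or resting T cell genes had a median of 0.19 (interval 0.07 to 0.32, 99.5th percentile), 0.12 without deleted plate 4. The 26 T cell receptor signalling genes lay at -0.03 (57.4th percentile, from -0.06 to 0.04 with 1 plate left out). Ubash3a (347 and 515 CPM) and Plcg1 (144 and 206 CPM) were separated. Nfatc2 alone was higher in that list, as were Ccr6 alone in the trafficking list and Dapl1 alone in the naive or resting list. None was lower in these lists.

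Cytosolic ribosomal protein genes were slightly lower in deleted hosts. Of the 72 cytosolic ribosomal protein genes, 63 were below a ratio of 1, with a median log2 ratio of -0.13 (interval -0.16 to -0.11, 0.03th percentile) that was -0.08 without control plate 4. Rpl32 was at 795 and 616 CPM and Rps28 at 122 and 85.9 CPM, both separated. Many ribosomal genes have processed copies in the genome, so these levels are uncertain. The 46 oxidative phosphorylation genes had a median of -0.14 (3.36th percentile), inside the middle 95% of random lists, and each lay within 2-fold, with Ndufa13 at 144 and 110.0 CPM. Glycolysis genes had a median of -0.08, with a direction that turned when 1 plate was left out (-0.18 without control plate 1 to 0.05 without control plate 3), and Pdk1, which limits pyruvate entry into mitochondria, was separated at 202 and 126 CPM. The 30 interferon response genes had a median of -0.09 that turned to 0.14 without control plate 3 and to 0.03 with a minimum of 20 CPM, with Irf9, a subunit of the interferon-activated complex ISGF3, separated at 216 and 118 CPM. Medians were 0.05 for cholesterol synthesis (-0.07 without control plate 1 or deleted plate 1 and -0.04 without deleted plate 3), 0.07 for the unfolded protein response (-0.09 without control plate 2), with Dnajb9 at 66.9 and 157 CPM, and 0.11 for apoptosis and survival (0.01 without control plate 3).

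Markers of other cell types were low in both pools beside the CD4 T cell markers, and the innate lymphoid sum alone had no overlap between plates. B cell markers summed to 84.9 CPM in control and 106 CPM in deleted hosts, plasma cell markers to 133 and 139.7 CPM, dendritic cell markers to 178 and 209 CPM, and monocyte or macrophage markers to 246 and 231 CPM. Neutrophil markers summed to 15.2 and 19.1 CPM, erythroid markers to 30.2 and 25.9 CPM, platelet markers to 43.4 and 22.7 CPM, and stroma or endothelium markers to 265 and 317 CPM. Innate lymphoid markers summed to 33.8 and 54.9 CPM, with control plates from 24.4 to 44.3 and deleted plates from 47.8 to 61.2. Of these 11 markers only 2 reached 5 CPM in either pool, with log2 ratios of 1.23 (Prf1) and 0.31. CD8 markers summed to 26.5 and 9.47 CPM. Only 1 of 11 stroma or endothelium markers and 2 of 7 plasma cell markers reached 5 CPM in either pool. Such sums can rest on very few genes and do not give amounts of other cells.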

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

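The tests in this part were chosen before their results were seen. Wells that should hold no cell carried reads, which drew attention because the control wells enter none of the comparisons. The 9 wells labelled noinput or dw held a median of 9554 reads in genes (6698 to 12348), 0.603% of a median cell of the same plate. Wells labelled mBM10 or mBM100 with over 100000 reads had a median of 6826.5 CPM of S100a8, a granulocyte gene, and 15068 CPM of Mpo, while their median Cd3e was 1.18 CPM. One mBM100 well, H10 of control plate 2, held 11622 reads, close to the wells without input.

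Reads assigned to the wrong well of a plate are a likely explanation for bone marrow reads in cell wells. For the reads in wells without a cell, the values did not decide it. Cell wells in the row or columns of the mBM wells held a median of 3.85 times the reads of 7 bone marrow genes seen in the other cell wells (2.19 to 4.67 over the 8 plates). For genes read almost only in 1 cell, 32.5% of their reads in a well without input came from cells of its row or column, which held 20.7% of the reads of these genes in their source cells, a ratio of 1.57 (interval 1.16 to 2.01) that 117 reads leave too uncertain to decide. Lyz2 at 12.03 CPM in control and 15.3 CPM in deleted hosts may therefore hold reads of the mBM wells, and no biological explanation was tested. The highest level in a well without input, scaled to a median cell, was 1.35 CPM for Dusp5, 4.29 CPM for Tnfaip3 and 3.02 CPM for Id3, far under their levels in the pools. For some genes read in few cells it was closer, such as 2.86 CPM for Ly6c2 (0.647 CPM in control and 6.11 CPM in deleted hosts), 1.88 CPM for Nfil3 (2.46 and 9.32 CPM) 1.91 CPM for Tmem176b (7.47 and 3.03 CPM), 1.32 CPM for Tbx21 (2.46 and 5.32 CPM), 0.714 CPM for Ifng (0.0907 and 3.46 CPM), 0.673 CPM for Il13ra1 (2.35 and 0.197 CPM) and 10.7 CPM for Ccl5 (6.35 and 11.9 CPM), so this background limits what such genes show.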

How the results depend on the processing

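Of 140 values of the 7 main list medians under other settings, 138 kept their direction within their interval over genes (for TH2 and TH17, the range of their members). Some of these ranges are wide, such as -0.46 to 1.72 for TH1 and -1.07 to 3.79 for TH17. The count therefore does not show that the sizes of the medians were stable. The TH1 median of 0.53 turned to -0.14 with a minimum of 20 CPM, which leaves 7 genes. With each plate left out in turn, the Treg median ranged from 0.21 to 0.999, TH1 from 0.01 to 0.83, TH17 from 0.37 to 2.21, TFH from 0.04 to 0.17, TFH-opposed from 0.19 to 0.37, TH2 from 0.02 to 0.44 and proliferation from 0.20 to 0.51. The lowest Treg, TH1 and TH17 values all came without deleted plate 3. Among named genes with 5 CPM or more that were at least 2-fold apart, the direction turned for 3 when 1 plate was left out. Their log2 ratios ranged from -0.30 to 1.78 for Sostdc1, from -0.10 to 2.47 for Ly6c2 and from -1.75 to 0.90 for Tmem176b. The cause was not tested beyond the few positive cells of these genes.

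Settings chosen after seeing the data were equal weights of cells, leaving out each gene's highest cell and a library size without LOC101056014 and mitochondrial genes. LOC101056014, a non-coding gene, took 5.95% of control and 7.59% of deleted-host reads. The median log2 ratio of all 9764 measured genes was -0.04, and between -0.05 and -0.01 under every setting, so no scaling moved it by over 0.1. Over all 24 lists, 475 of 480 values stayed within their interval and 465 kept their direction, with the same limit for lists with wide intervals. Of 3330 values for 185 named genes, 3253 kept their direction, but only 968 stayed within the counting interval of their ratio. No paired analysis was possible because each group is 1 pooled sample and no test was run.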

Other observations

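The tests on single bright cells were chosen after values without the highest cells were seen, and the other tests before their results were seen. Clusters built without the separated, activation and immediate early genes had shares with overlapping intervals in the pools. The genes named here were higher in their cluster than in the other cells. Cd44 and Tnfrsf9, as activation genes, were not used to build the clusters. Cluster 1, with higher Tsc22d3, Txnip and Cmah, held 59.0% of control cells (interval 53.8 to 64.0%) and 62.1% of deleted-host cells (56.9 to 67.1%). Cluster 2, with higher Cd44, Cd82, Lgals1 and S100a11, held 31.5% (26.8 to 36.5%) and 25.3% (21.0 to 30.1%). Cluster 3, with higher Tnfrsf9, Nfkb2 and genes of ribosome assembly such as Nop16, held 9.51% (6.71 to 12.98%) and 12.5% (9.32 to 16.4%). Deleted plates ranged from 16.5 to 37.0% for cluster 2, wider than the gap between the pools.

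Differences in the abundant separated genes appeared within clusters. Dusp5 was at 32.8 CPM in control and 203 CPM in deleted hosts in cluster 1, at 41.0 and 189.9 CPM in cluster 2, and at 42.0 and 333 CPM in cluster 3. Tnfaip3 was at 143 and 507 CPM in cluster 1 and 108 and 628 CPM in cluster 2, but at 206 and 300.1 CPM in cluster 3. Egr1 was at 362 and 87.5 CPM in cluster 1, 228 and 148 CPM in cluster 2, and 158 and 166 CPM in cluster 3. Of the 15 abundant separated genes, 14 had the pool's direction in all 3 clusters, with Egr1 as the exception.

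These 15 genes, among them Dusp5, Tnfaip3, Rgs2, Junb and Id3, form a pattern for which 3 technical explanations were weighed. Reweighting the deleted pool to the control pool's clusters left at least 0.955 of each log2 ratio (at least 0.912 with 6 clusters). A different mix of these clusters is therefore unlikely. The clusters were built without the separated, activation and immediate early genes. A different mix of cells in states that mainly those genes mark cannot be judged this way. Without the highest cell of each pool, at least 0.980 of each ratio was left. The genes had been picked for plates without overlap, which 1 cell on 1 plate could hardly produce. This value therefore adds little on single bright cells beyond the selection itself. Plate processing or handling that differed between the pools cannot be told apart from the receptor deletion, because 0 plates held cells of both. Differences between individual mice (2 and 3 in the pools) and other differences between the host strains cannot be told apart from the deletion either. All of these, and an effect of the deleted hosts on the signals that T cells receive, stay open. Stress genes, picked after their values were seen, do not settle it, since the chaperone genes of the immediate early and heat shock list had log2 ratios from 0.12 (Hspa8) to 0.31 (Hsp90aa1), while Fos was at 452 and 618 CPM and Ppp1r15a, which ends a block of translation under stress, was separated at 382 and 765 CPM.

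Lists that describe opposed fates (TFH, TFH-opposed, TH1, TH17, Treg and naive or resting T cell) lay above the middle 95% of random lists in deleted hosts. The TH2 list, at the 81.5th percentile, did not. The lowest medians with 1 plate left out were 0.04 for TFH, 0.01 for TH1 and 0.37 for TH17. They were 0.21 for Treg and 0.119 for naive or resting T cell. These lie under the upper ends of the full pools' random ranges (0.12, 0.38, 1.10, 0.26 and 0.124). For TFH-opposed the lowest was 0.19, above 0.13. Gene length or GC bias is an unlikely source, because 6 of 6 stayed above the middle 95% when random lists were also matched on transcript length and GC content, and the log2 ratio had rank correlations across genes of 0.05 with length and 0.01 with GC content. Without the highest cell of each pool for each gene, 4 of the 6 lists stayed above the middle 95%. A single bright cell per gene is therefore an unlikely source for those. Several bright cells per gene cannot be judged this way, since only the highest was left out. For TH1 and TH17 a single bright cell per gene stays open as a source. Their medians fell below the upper end of the random range but within their own spread. The TH1 median went from 0.53 (interval -0.46 to 1.72) to 0.36 (-0.52 to 1.66, 96.2nd percentile), under the random range's upper end of 0.41, and TH17 from 1.51 (members -1.07 to 3.79) to 0.76 (-1.39 to 2.74, 89.9th percentile), under 1.31. The TH2 list rose to the 99.4th percentile. Plate processing or handling that differed between the pools cannot be told apart from the deletion here either, with 0 plates shared. The same direction for opposed lists suggests that none of them by itself marks a shift of fate, a reading that only separate animals could test.

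Gapdh, picked after its values were seen, was at 5.07 CPM in control and 8.63 CPM in deleted hosts, far below Pgk1 at 121 and 145 CPM.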
